A study of Mus musculus with 12 samples.

How the data were processed

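Gastrocnemius RNA of 6 female mice aged 11 weeks was sequenced by the submitters from both lower legs, giving 12 libraries in 4 groups of 3. Libraries were prepared with a QuantSeq 3' mRNA kit from Trizol-extracted RNA, per the labels' protocols. The series holds 1 table of gene counts, which the authors deposited as whole reads per gene, not normalized. FastQC 0.11.5, STAR 2.5.2a, SAMtools and HTSeq 0.6.0 with genome build mm10 are named in the submitters' processing notes, which give neither roles nor order. The annotation release, trimming, strand setting and any filter are not stated, and the deposited table is described as modified without saying how. Because no strand setting is stated, reads of overlapping or antisense genes cannot be told apart. How Myc was over-expressed and how long after contraction the muscle was taken are also not stated.

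The table held 47643 gene identifiers, of which 47224 were paired with a symbol in the reference list of names and 419 were not. Those 419 took at most 0.0128% of a library's reads. In all, 29772 genes had no read in any library. Groups came from the titles, which give genotype, animal number and leg. The left leg was the uncontracted and the right the contracted leg in every animal. Total counts ranged from 1371732 to 1643216, and 3 reads, the limit that a count of 0 allows, equalled 1.83 to 2.19 CPM, that is, counts scaled to a common library total. Intervals for single counts are exact Poisson intervals at 95%, and for ratios exact intervals from the split of the pooled reads. These intervals and limits cover counting error only, since reads without molecular identifiers are not independent molecules. The 10 highest genes took 45.1 to 51.8% of reads, and the mitochondrial gene mt-Nd4 alone 21.1 to 29.4%.

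The 5 planned comparisons were contraction in each genotype, Myc in each leg, and their interaction. Each was tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr with a minimum count of 10, quasi-likelihood fit and F test, 2-sided, all 12 libraries and 4 group means). Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over the 6676 genes tested. Each SE of a log2 change is the size of the change divided by the square root of its F statistic. It thus restates the test, was not estimated separately, and can be too small where a group has few reads. The comparisons, tests, alternatives, gene lists and rule for named genes were fixed before the data were examined. The contraction effect averaged over both genotypes, and every fit that leaves out the 4 contracted libraries numbered 2 and 3, were chosen after seeing the data. Those 4 were chosen because their Myc reads go against their labels, and libraries were placed in other groups only to count all other splits of a comparison.

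Gene lists, 33 in all, cover immediate early, metabolic, cytokine, heat shock, mechanical, ribosome production, energy metabolism, fibre type, proteolysis, myogenic, cell cycle, stress, clock and MYC network genes, and markers of 10 other cell types. The 31 lists with at least 3 measured genes were tested with camera in limma 3.58.1 on voom log2 CPM with a preset correlation of 0.01, adjusted over the lists of a comparison. Camera was repeated with the correlation estimated from the residuals, and fry was run. Fry asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes. Hk2 and Ucp3 are each in the list of metabolic regulators and in a list of energy metabolism.

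Named genes are Myc, then in each simple comparison the 10 highest and 10 lowest changes among genes that passed, whose groups did not overlap and whose mean was at least 5 CPM, leaving out unnamed gene models and pseudogenes. For each list up to 4 genes with the smallest p could be named, and among these the text gives a selection made after their values were seen. List scores per library are mean log2 CPM of the measured members, with a prior count of 2, minus the mean of the 12 libraries.

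Alternatives were other scalings (RLE, library totals alone), DESeq2 1.42.0, robust dispersions, no low-count filter or a stricter one (20 reads in 3 libraries), the 6 libraries compared alone, each library left out in turn, and the animal as a fixed or random block. Legs with the same number and genotype come from the same animal, per the titles. Within such pairs the deviations from the group means correlated at -0.122 to 0.112 over the 6 animals, and the consensus correlation of the random block was 0.00101. For comparisons that share libraries, 50 simulated sets of unchanged groups gave the value expected without effects.

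The steps were tested on simulated counts drawn from the real means, library sizes and dispersions, with 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold. In the simulated contraction comparison of controls, edgeR recovered 23.9%, 53.7% and 97.0% of them over 6676 genes, with 2 false calls. In the simulated Myc comparison of contracted legs it recovered 8.96%, 52.2% and 92.4% with 9 false calls. A list shifted by 1.3-fold was called by camera and 0 of 30 unshifted lists were. Genes were drawn independently in this single simulated set, so it does not show how often camera calls unshifted lists of correlated genes. Figures were drawn with matplotlib 3.10.9.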

Results

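Messenger RNA was counted from its 3' ends in the gastrocnemius, a calf muscle, of 11-week-old female mice that were either controls or over-expressed c-myc (Myc), a transcription factor that drives cell growth and ribosome production. The 6 animals, 3 of each genotype, each gave an uncontracted left leg and an acutely contracted right leg, so that the 12 libraries formed 4 groups of 3. Contraction and body side cannot be separated in this design. Total counts were 1371732 to 1643216 per library (median 1526524), and 6676 genes had enough reads to be tested. At this depth 1 read was worth 0.609 to 0.729 CPM (counts scaled to a common library total). Mitochondrial transcripts took 27.1 to 35.2% of the reads.

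Myc itself, the targeted gene, was examined first because it checks the labels. The uncontracted libraries labelled control 1, 2 and 3 held 0, 1 and 0 Myc reads, and the uncontracted libraries labelled Myc 1, 2 and 3 held 11, 9 and 9. In the contracted legs the libraries labelled control 1, 2 and 3 held 1, 10 and 59 reads, and those labelled Myc 1, 2 and 3 held 32, 0 and 2. Myc reads therefore went against the label in the contracted libraries numbered 2 and 3 of both genotypes. The library labelled contracted control 3 had the highest level of the 12, at 39.9 CPM (95% exact Poisson interval 30.4 to 51.5). The library labelled contracted Myc 2 had 0 reads, with an exact interval up to 2.245 CPM (1.83 CPM by the limit of 3 reads). Pooled over 3 libraries, uncontracted legs labelled Myc had 31.2 times the Myc reads of those labelled control (5.16 to 1270, and 20.5 without uncontracted control 1), and contracted legs labelled Myc had 0.467 times (0.300 to 0.713). The contracted ratio rests on single libraries, since it was 1.99 (0.985 to 4.35) without the library labelled contracted control 3, which holds 59 of the 70 control reads, and 0.0396 without contracted Myc 1. It was 0.720 without contracted Myc 2 and 0.316 to 0.666 without any other contracted library. A 2-sided exact permutation test on 3 against 3 libraries gave p = 0.1 in uncontracted legs, the smallest it can give, and p = 0.6 in contracted legs. A 3' tag library does not count a transgene that lacks the endogenous 3' end, and the labels do not describe the construct. All directions below follow the labels as deposited.

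**Figure D1:**
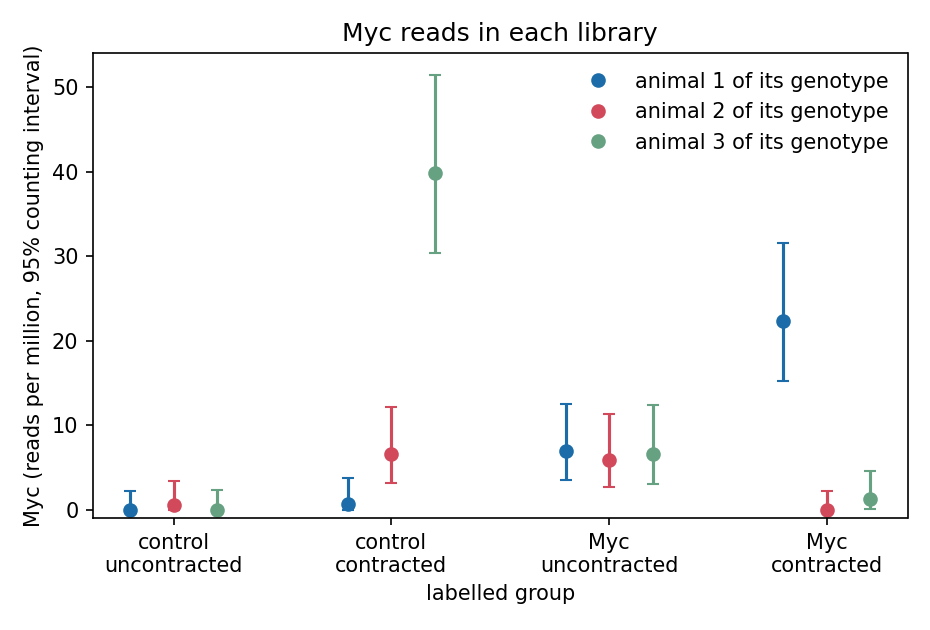
Myc CPM in each of the 12 libraries (points) with 95% exact counting intervals (bars), by labelled group on the x axis and coloured by animal number within genotype. The contracted libraries labelled control 3 and Myc 1 are highest, at 39.9 and 22.3 CPM, and the contracted library labelled Myc 2 holds 0 reads.

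The contracted and uncontracted legs labelled control were compared to ask what acute contraction changes in muscle without added Myc. Genes that respond to mechanical load and to stress were among those that rose. Rrad, a small GTPase that restrains calcium channels, went from 1.09 ± 0.410 to 129 ± 20.2 CPM (SD, n = 3), a log2 change of 6.80 ± 0.51 (SE). Ankrd1, a load-sensitive partner of the giant muscle protein titin, rose by 5.99 ± 0.41, and the actin-binding protein gene Xirp1 by 3.53 ± 0.32. The stress-induced transcription factor gene Atf3 rose by 4.70 ± 0.61, and Socs3, an inhibitor of cytokine signalling, by 3.82 ± 0.56. In all, 187 genes passed edgeR's test, 159 higher and 28 lower, of which 140 changed by more than 2-fold.

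Among the gene lists, 10 of 22 measured immediate early genes rose and 12 did not pass (13 rose when adjusted over the list alone). They included Egr1 (3.58 ± 0.41), Klf6 (2.90 ± 0.34) and Btg2 (2.21 ± 0.31), and the list ranked above other genes by camera (adjusted p = 3.14e-12, and adjusted p = 0.154 with an estimated correlation). Of 28 heat shock and chaperone genes 13 rose and 15 did not pass (15 rose and 1 fell when adjusted over the list alone), among them the small heat shock protein genes Hspb8 (1.67 ± 0.21) and Cryab (1.06 ± 0.13). That list's camera adjusted p was 6.54e-13, with adjusted p = 0.0797 with an estimated correlation. Hspa1a (3.26 ± 0.46) and Hspa1b are near-identical copies, so the division of reads between them is uncertain. Hspa1b had 131 reads against 3, a ratio of 46.7 (15.6 to 229), which was 95.1 without uncontracted control 3 and 30.7 without uncontracted control 1.

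Of 17 genes of mechanical stress and sarcomere remodelling 7 rose and 10 did not pass (10 rose when adjusted over the list alone), including Mustn1 (5.66-fold) and the growth factor gene Hbegf (2.66 ± 0.23). The camera adjusted p was 4.30e-12, with adjusted p = 0.0797 with an estimated correlation. Of 6 measured cytokine and myokine genes 3 rose (5 when adjusted over the list alone), including Socs3 and Timp1 (29 reads against 3, a ratio of 10.3, 3.20 to 53, which was 20.4 without uncontracted control 1 and 6.84 without uncontracted control 2). This list gave a camera adjusted p = 8.01e-05 and adjusted p = 0.171 with an estimated correlation. Of 61 genes of rRNA processing and nucleolar assembly 7 rose and 54 did not pass (15 rose when adjusted over the list alone), among them Rrp1b (1.82 ± 0.35), Rrs1 (1.28 ± 0.28) and Wdr43 (0.87 ± 0.21). The camera adjusted p was 2.68e-10, with adjusted p = 0.171 with an estimated correlation. None of 76 cytosolic ribosomal protein genes passed alone in edgeR, but their median log2 change was 0.21 and the list ranked above other genes (camera adjusted p = 1.49e-07, and adjusted p = 0.485 with an estimated correlation). That rise lay in the libraries labelled contracted control 2 and 3, with scores of 0.0629 and 0.168, while contracted control 1 scored -0.178, inside the uncontracted range of -0.342 to -0.134. Without the 4 contracted libraries numbered 2 and 3 the median of ribosomal protein genes was 0.00685 and camera's direction was reversed, and the rRNA processing list no longer passed (median 0.19).

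Among translation initiation and aminoacyl-tRNA synthetase genes, 1 of 36 rose (1 also when adjusted over the list alone), Eif1a (1.82 ± 0.26), with a camera adjusted p = 0.000498 and adjusted p = 0.0797 with an estimated correlation. The 16 fast fibre contractile genes had a median of -0.26 and the 23 genes of glycolysis and glycogen use a median of -0.14, with camera adjusted p = 6.13e-05 and 0.000451 (adjusted p = 0.217 with an estimated correlation for both). In the glycolysis list Hk2, which encodes hexokinase 2, rose by 1.89 ± 0.31, and Slc16a3, which encodes a lactate exporter, fell by 0.61 ± 0.13. The 4 haemoglobin genes of the erythrocyte list had a median of 0.58 (camera adjusted p = 0.0148, and adjusted p = 0.382 with an estimated correlation), and 7 smooth muscle and pericyte genes a median of -0.46 (camera adjusted p = 0.0447, and adjusted p = 0.217 with an estimated correlation). Without the 4 contracted libraries numbered 2 and 3 the translation, glycolysis, fast fibre and smooth muscle lists no longer passed, with medians of 0.01, -0.01, -0.02 and -0.36. The haemoglobin list did not pass without the library labelled uncontracted control 3 (median 0.30) or contracted control 1 (0.24). The smooth muscle list did not pass without uncontracted control 2 (-0.45) or 3 (-0.34) or contracted control 1 (-0.47).

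Genes that rose in lists that did not pass included Ppargc1a (1.94 ± 0.36), the coactivator of mitochondrial biogenesis, and Hmox1 (2.19 ± 0.46) among metabolic regulators. The metallothionein genes Mt1 (3.12 ± 0.31) and Mt2 (3.27 ± 0.32) and the muscle ubiquitin ligase gene Trim63 (1.60 ± 0.28) rose in the atrophy, autophagy and proteolysis list. The myogenic factor genes Myod1 (2.52 ± 0.37) and Myf6 (2.17 ± 0.49) rose in the regeneration list, and Uck2 (1.99 ± 0.31) and Srm (1.20 ± 0.25) in the nucleotide and polyamine list. Of the 2 measured neutrophil markers, S100a8 had 143 reads against 6 (log2 change 4.56 ± 0.92) and S100a9 had 47 against 1, a ratio of 50.2 (8.59 to 2026). The S100a8 reads were 0, 2 and 4 in uncontracted control 1, 2 and 3, and 63, 9 and 71 in the contracted ones. Without contracted control 3 the S100a9 ratio was 27.1, without uncontracted control 1 or 2 it was 33.1 or 33.3, and uncontracted control 3 held the only uncontracted read. The transcription factor gene Runx1 had 42 reads against 2 (ratio 22.4, 5.84 to 191, and 14.9 without uncontracted control 2) and Sgms2, a sphingomyelin synthase gene, 40 against 2 (21.4, 5.54 to 183, and 14.1 without uncontracted control 1). Genes that fell included Arrdc2 (-2.12 ± 0.43), Odf3l2 (-1.98 ± 0.34), the methyltransferase gene Inmt (-1.94 ± 0.28) and the Wnt antagonist gene Frzb (-1.74 ± 0.41). The clock gene Per3 fell by 1.38 ± 0.23, and Csf1r, the macrophage growth factor receptor gene, by 0.80 ± 0.21.

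The remaining lists did not pass in this comparison. Camera adjusted p was 0.0530 for metabolic regulators and for nucleotide, one-carbon and polyamine synthesis, 0.0785 for fatty acid oxidation, 0.111 for the RNA polymerase I machinery, 0.172 for fibroblast and 0.195 for circadian clock genes. It was 0.322 for proteasome subunits, 0.413 for endothelial and for tendon markers, 0.467 for myogenic genes and 0.474 for macrophage markers. It was 0.685 for the MYC network, 0.707 for slow fibre, atrophy, cell cycle, p53 and adipocyte genes, 0.726 for ATF4 and Schwann cell genes, and 0.985 for oxidative phosphorylation. The lymphocyte list had 1 measured gene, Ighm, with a log2 change of -0.77 ± 0.43, and was not tested, like the neutrophil list. Groups did not overlap in 185 of the 187 genes and in 1122 (16.8%) of all 6676, against 10% by chance, and genes that passed are selected for such a gap. The count was 313 without the library labelled contracted control 1, 116 without that labelled contracted control 3, and 67 without the 4 contracted libraries numbered 2 and 3. Myc, whose reads go against the labels here, had a log2 change of 5.72 ± 1.59 (edgeR adjusted p = 0.0591, and 0.0131 with the animal as a block). It was 3.69 without contracted control 3, and passed without contracted control 1 (6.25) or 2 (6.08).

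The same comparison in animals labelled Myc asks how muscle with added Myc responds to contraction. Rrad (6.59 ± 0.50), Ankrd1 (5.77 ± 0.41), Atf3 (5.45 ± 0.66), Egr1 (4.32 ± 0.44), Socs3 (4.24 ± 0.58) and Xirp1 (4.11 ± 0.32) rose again. The nuclear receptor gene Nr4a3 rose by 4.34 ± 0.52. Fos, the founding immediate early gene, had 93 reads in contracted legs and 0 in uncontracted legs, at least 29.6-fold higher against a floor of 3 reads over the group (19.2 without uncontracted Myc 1 and 19.6 without uncontracted Myc 2). In all, 260 genes passed edgeR's test, 230 higher and 30 lower, of which 190 changed by more than 2-fold.

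Of 22 immediate early genes 14 rose (16 when adjusted over the list alone), with a median of 1.98, which is 1.98 also with Fos at its bound. They included Btg2 (3.13 ± 0.34), Klf6 (3.31 ± 0.36) and Jund (1.44 ± 0.17), and Csrnp1 had 51 reads against 2, a ratio of 24.4 (6.41 to 207), which was 15.8 without uncontracted Myc 1, and uncontracted Myc 2 held both uncontracted reads. The list's camera adjusted p was 5.93e-18, with adjusted p = 0.108 with an estimated correlation. Of 17 genes of mechanical stress and sarcomere remodelling 9 rose (13 when adjusted over the list alone), including Mustn1 (2.90 ± 0.19) and Hbegf (2.65 ± 0.24), with camera adjusted p = 3.39e-16 and adjusted p = 0.0975 with an estimated correlation. Of 28 heat shock and chaperone genes 10 rose (11 when adjusted over the list alone), including Hspb7 (1.56 ± 0.16), Hspb8 (1.93 ± 0.21) and Hspb1 (1.97 ± 0.23), with camera adjusted p = 9.74e-08 and adjusted p = 0.178 with an estimated correlation. Of 6 cytokine and myokine genes 3 rose (6 when adjusted over the list alone), including Socs3 and Timp1 (2.51 ± 0.56), with camera adjusted p = 0.000118 and adjusted p = 0.262 with an estimated correlation.

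Of 12 myogenic and regeneration genes 3 rose (5 when adjusted over the list alone), Myod1 (3.05 ± 0.37), the hepatocyte growth factor receptor gene Met (1.36 ± 0.28) and Myf6, with camera adjusted p = 0.00130 and adjusted p = 0.322 with an estimated correlation. Of 15 ATF4 and endoplasmic reticulum stress genes 2 rose (3 when adjusted over the list alone), including Atf4 (0.91 ± 0.15), with camera adjusted p = 0.0177 and adjusted p = 0.458 with an estimated correlation. That list did not pass without the library labelled uncontracted Myc 2 (median 0.27) or contracted Myc 2 (0.20), or without the 4 contracted libraries numbered 2 and 3 (0.09). Both adult alpha-globin genes rose, Hba-a1 by 1.02 ± 0.20 and Hba-a2 by 1.06 ± 0.26, although the division of reads between such near-identical copies is uncertain. The erythrocyte list of 4 haemoglobin genes had a median of 1.01 (camera adjusted p = 0.000474, and adjusted p = 0.322 with an estimated correlation). None of 76 ribosomal protein genes and none of 72 nuclear oxidative phosphorylation genes passed alone in edgeR, with medians of -0.20 and -0.11. Their camera adjusted p was 1.86e-07 and 0.000120, with adjusted p = 0.497 with an estimated correlation for both. The lower ribosomal protein values lay in the libraries labelled contracted Myc 2 and 3 (scores -0.140 and -0.0861), while contracted Myc 1 scored 0.286, above the uncontracted range of 0.104 to 0.234. Without the 4 contracted libraries numbered 2 and 3 the ribosomal protein median was 0.11, with camera's direction reversed, and the oxidative phosphorylation list no longer passed (median 0.02).

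Outside these lists Ppargc1a (2.60 ± 0.39), Hk2 (1.91 ± 0.31), Mt1 (3.18 ± 0.31), Mt2 (3.19 ± 0.32) and Trim63 (2.02 ± 0.28) rose. S100a8 had 73 reads against 0, at least 23.3-fold higher, and S100a9 had 41 against 0, at least 13.1-fold higher, both against a floor of 3 reads over the group. Without the library labelled contracted Myc 3 these bounds were 10.1 and 5.80, without uncontracted Myc 1 they were 15.1 and 8.45, and without uncontracted Myc 2 15.4 and 8.63. Cd68, a macrophage lysosomal marker, rose by 2.32 ± 0.58. Genes that fell included Inmt (-2.90 ± 0.29), Odf3l2 (-2.44 ± 0.34), Plekhh3 (-1.57 ± 0.43), Slc25a25 (-1.38 ± 0.38) and Zfp503 (-1.35 ± 0.33). The clock output gene Dbp fell by 1.25 ± 0.22 and Per3 by 0.98 ± 0.24. Groups did not overlap in 249 of the 260 genes and in 1304 (19.5%) of all 6676, against 10% by chance. Without 1 library at a time the count was 517 (contracted Myc 1), 152 (contracted Myc 2), 147 (contracted Myc 3), 151 (uncontracted Myc 2) and 173 (uncontracted Myc 3), and it was 59 without the 4 contracted libraries numbered 2 and 3. Myc had a log2 change of 0.17 ± 0.98 as labelled (edgeR adjusted p = 0.964), but -3.26 without contracted Myc 1, which holds 32 of the 34 contracted reads, 0.77 and 0.69 without contracted Myc 2 and 3, 0.07 without uncontracted Myc 2, and -0.0659 with the animal as a block.

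**Figure D2:**
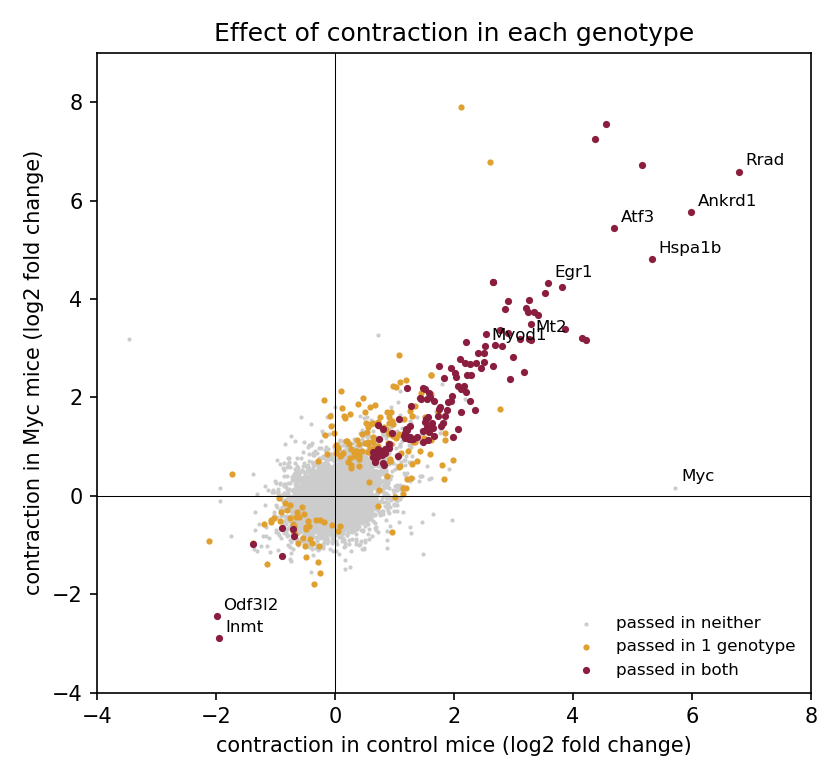
Log2 fold change with contraction in animals labelled control (x axis) and Myc (y axis) for each of the 6676 tested genes, coloured by whether the gene passed edgeR's test in neither, 1 or both genotypes. Rrad, at 6.80 and 6.59, and Ankrd1, at 5.99 and 5.77, lie near the diagonal, and the 134 genes that passed in both comparisons changed the same way in each.

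The responses in both genotypes shared 134 genes, 127 that rose and 7 that fell, where independent lists of these sizes would share 5.48 and 0.126. Across the 6676 genes the log2 changes had Pearson's r = 0.634 and Spearman's rho = 0.380, and genes are not independent replicates. The r was 0.277 without the 4 contracted libraries numbered 2 and 3. Averaging contraction over both genotypes, a comparison added after the data were seen because exchanging genotype labels among contracted legs does not alter the legs compared, gave 499 genes in edgeR, 381 higher and 118 lower. It was 107 without the 4 contracted libraries numbered 2 and 3. Rrad (6.69 ± 0.36) and Ankrd1 (5.88 ± 0.29) rose again, and Inmt fell by 2.42 ± 0.20.

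The uncontracted legs of both genotypes were compared to ask what Myc changes in resting muscle. Genes of ribosome production and nucleotide synthesis had higher values in legs labelled Myc, by less than 2-fold for most members. All but 1 of 76 cytosolic ribosomal protein genes were higher (median 0.38), as were 52 of 61 rRNA processing genes (median 0.37) and 22 of 24 genes of nucleotide, one-carbon and polyamine synthesis (median 0.37). Nme1, a nucleoside diphosphate kinase gene, had 54.1 CPM against 25.0 (log2 change 1.11 ± 0.21, edgeR adjusted p = 0.117). The nucleolar gene Ncl had a log2 change of 0.76 ± 0.17 (adjusted p = 0.314), and Gnl3 and Srm had 1.07 ± 0.30 and 0.91 ± 0.26 (adjusted p = 0.541 for both).

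The nucleotide, one-carbon and polyamine list ranked above other genes by camera (adjusted p = 5.91e-06), also with an estimated correlation (adjusted p = 0.0226), and its fry adjusted p was 0.0132. None of its genes passed alone, and 2 rose when adjusted over the list alone. For ribosomal proteins the camera adjusted p was 9.43e-41 (28 of 76 rose when adjusted over the list alone), for rRNA processing 5.71e-10, for oxidative phosphorylation 2.14e-10, for translation 0.0187 and for the RNA polymerase I machinery 0.0369. Lower in legs labelled Myc were fast fibre genes (2.21e-05), fibroblast and matrix markers (6.05e-05), macrophage markers (0.0124) and tendon markers (0.0136). Each of these 9 lists had adjusted p = 0.209 with an estimated correlation. Immediate early genes were lower (median -0.53, camera adjusted p = 0.00407), as were glycolysis genes (-0.11, 0.00752), and heat shock genes were higher (0.09, 0.0130). Their adjusted p = 0.488, 0.328 and 0.420 with an estimated correlation, in that order. Without the library labelled uncontracted control 3 the macrophage (median -0.15), fibroblast (-0.13), heat shock (0.14) and RNA polymerase I (0.17) lists did not pass. Without uncontracted control 2 the tendon (-0.32), translation (0.17), glycolysis (-0.08) and RNA polymerase I (0.10) lists did not pass. The macrophage list also did not pass without uncontracted Myc 2 (-0.30), the translation list without uncontracted Myc 1 (0.14), and the RNA polymerase I list without uncontracted Myc 1 (0.13), 2 (0.18) or 3 (0.12). The collagen gene Col1a1 had a log2 change of -1.02 ± 0.28 (adjusted p = 0.541).

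No gene passed edgeR's test in this comparison, with 421 at an unadjusted p under 0.05, while DESeq2 called 1 gene and limma-voom with a random animal block 0. That gene, named after its values were seen, was Timm10, a mitochondrial import chaperone gene, with a log2 change of 1.29 in DESeq2 (adjusted p = 0.0456). Myc had a log2 change of 4.48 ± 1.92 (edgeR adjusted p = 0.702). Without the 4 contracted libraries numbered 2 and 3, whose spread enters the shared estimate, edgeR called 6 genes, namely Timm10, Nme1, Ncl, Rpl36a, Col1a1 and Myc, and the call of Myc carries no information, since those libraries were chosen by their Myc reads. The other calls rest on the same choice of libraries, which may also lower the spread of genes that vary with Myc. They are thus not independent evidence of a Myc effect, and in all libraries the smallest edgeR adjusted p was 0.117. In simulated data of this design edgeR recovered 49.3% of genes changed 2-fold and 8.96% of genes changed 1.5-fold.

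**Figure D3:**
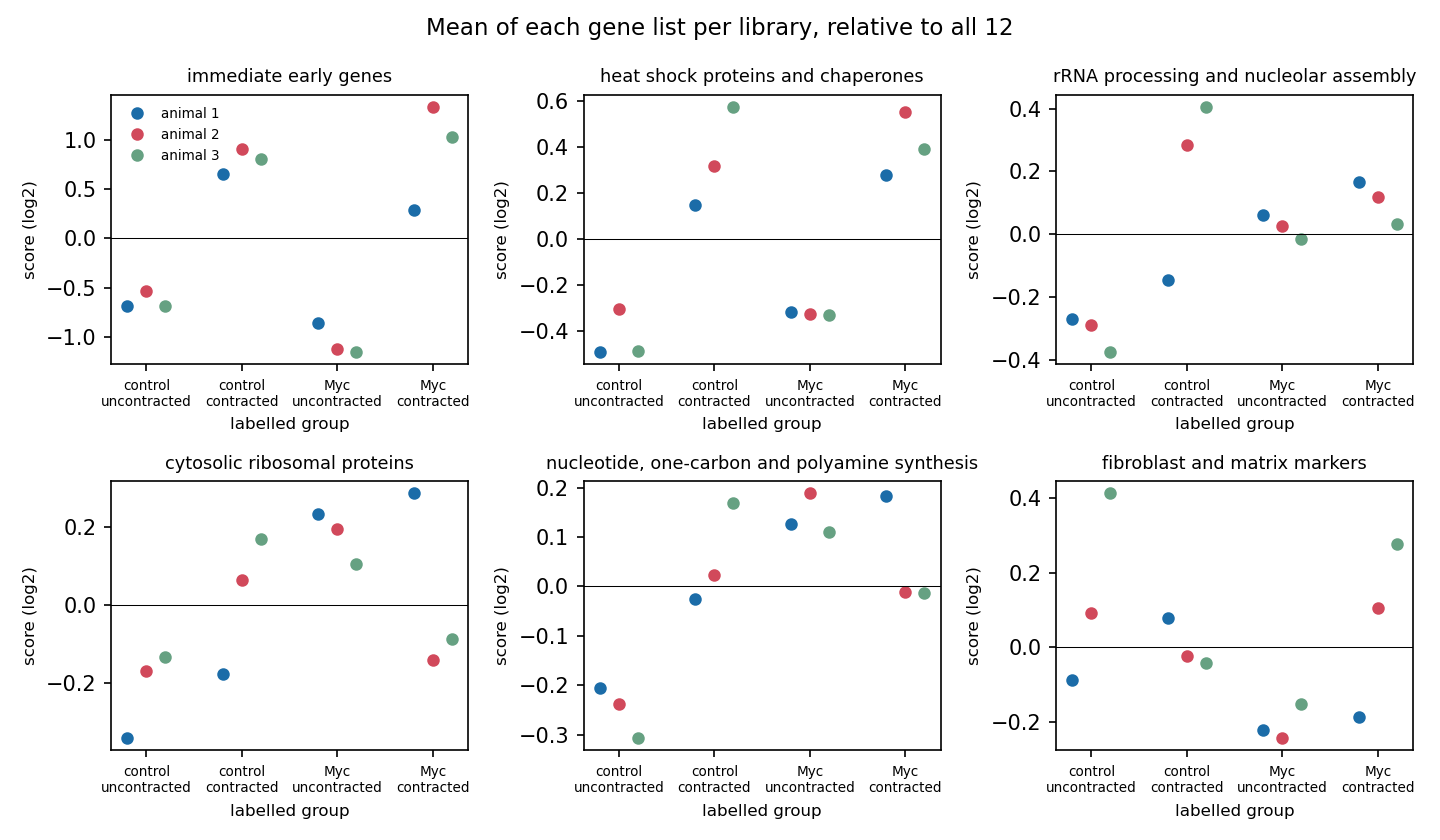
Mean log2 level of 6 gene lists in each library relative to the mean of all 12 libraries (y axis), by labelled group and coloured by animal number within genotype. Ribosomal protein scores lie between -0.342 and -0.134 in uncontracted libraries labelled control and between 0.104 and 0.234 in those labelled Myc, while in contracted legs the libraries labelled Myc 2 and 3 score -0.140 and -0.0861.

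The contracted legs of both genotypes were compared to ask what Myc changes in contracted muscle. Ribosomal protein genes, with a median log2 difference of -0.01, and nucleotide synthesis genes, at -0.05, did not differ as labelled (camera adjusted p = 0.607 and 0.840). The library labelled contracted Myc 1 scored 0.286 for ribosomal proteins, against -0.140 and -0.0861 in those labelled contracted Myc 2 and 3. No gene passed edgeR's test, with 204 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom, and none of the 31 lists passed camera. Without the 4 contracted libraries numbered 2 and 3, which leaves 1 library on each side, 12 lists passed camera and 0 genes passed edgeR. Without 1 contracted library at a time, the lists called were 5, 2 and 3 (control 1, 2 and 3) and 8, 3 and 1 (Myc 1, 2 and 3). Myc, whose reads go against these labels, had a log2 difference of -1.07 ± 0.84 (adjusted p = 0.999), and 0.97 without the library labelled contracted control 3. Without any other contracted library it lay between -4.50 (contracted Myc 1) and -0.46 (contracted Myc 2). The Myc effects in uncontracted and contracted legs had r = -0.0505 and rho = -0.0210 across genes, and r = 0.127 without those 4 libraries. Without 1 library at a time that r lay between -0.167 (contracted Myc 1) and 0.0217 (contracted Myc 2), and it was above 0 also without contracted Myc 3 (0.00436).

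The interaction asks whether contraction acts differently with added Myc. Genes of ribosome production had lower values for the contraction effect in animals labelled Myc, with a median interaction of -0.39 for ribosomal proteins, -0.48 for rRNA processing and -0.45 for nucleotide synthesis. Immediate early genes had a median of 0.73, and fibroblast and matrix genes 0.37. Listed genes with small unadjusted p included Nme1 (-1.06 ± 0.30), Ncl (-0.91 ± 0.24), Rpl27 (-0.81 ± 0.22), Dusp1 (1.29 ± 0.36) and Col1a1 (1.37 ± 0.39), each with edgeR adjusted p = 0.854. No gene passed edgeR's test, with 331 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom, and 12 lists passed camera. None of the 12 passed with an estimated correlation, the smallest being adjusted p = 0.0744 with an estimated correlation for nucleotide synthesis. Without the library labelled contracted Myc 1 edgeR called 4 genes (Timm10, Sparc, Tfrc and Rps19), and without contracted control 1 or 3 it called Timm10 or mt-Tp, all named after their values were seen. Without the 4 contracted libraries numbered 2 and 3, whose Myc reads go against their labels, 1 list and 0 genes passed, with fewer legs to test on. The median interaction was then 0.07 for ribosomal proteins and -0.04 for rRNA processing, with camera's direction reversed in both lists. It was 0.03 for immediate early genes and -0.13 for nucleotide synthesis, but -0.44 for the RNA polymerase I machinery against -0.29 in all libraries. In simulated data 17.9% of genes with a 2-fold interaction were recovered.

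The contraction effect in animals labelled control and the Myc effect in uncontracted legs share the uncontracted control libraries. Their log2 changes had r = 0.240 and rho = 0.318 across genes, where unchanged groups simulated against those libraries gave r = 0.489. The r was 0.404 without the library labelled uncontracted control 3 and 0.160 without uncontracted Myc 1. The covariance was 0.0455 against 0.0489 simulated, a difference of -0.00342. With the Myc effect in contracted legs, where the shared libraries bias the value the other way, r was -0.223 against -0.509 simulated, and the covariance differed by 0.0163. For contraction in animals labelled Myc, r was -0.427 with the Myc effect in uncontracted legs (simulated -0.512, covariance difference -0.0389) and 0.336 with that in contracted legs (simulated 0.489, covariance difference 0.00930). The simulated covariances had SDs of 0.00143 to 0.00171. Genes were drawn independently in the simulation, so these SDs leave out spread that genes share and cannot be used to judge the differences. The comparisons of this paragraph include the 4 libraries whose Myc reads go against their labels. Because 0 genes passed for Myc, no overlap of calls could be formed.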

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

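All tests that weigh explanations in this part were chosen after the Myc reads and the list values had been seen, while the interaction tests were planned. In 12 lists the effect of contraction differed between genotypes as labelled, by camera's test of the interaction with the preset correlation. The median interaction (log2) was 0.73 for immediate early genes, -0.29 for the RNA polymerase I machinery, -0.48 for rRNA processing, -0.39 for ribosomal proteins, -0.45 for nucleotide, one-carbon and polyamine synthesis and -0.16 for translation genes. It was -0.11 for oxidative phosphorylation, 0.15 for glycolysis, 0.21 for fast fibre genes, 0.41 for myogenic genes, 0.36 for ATF4 and endoplasmic reticulum stress and 0.37 for fibroblast and matrix markers. With an estimated correlation 0 of the 12 passed, with adjusted p from 0.0744 to 0.423. Leaving out 1 library ended the call of the RNA polymerase I list (without uncontracted control 2, median -0.37), of glycolysis (contracted control 3, 0.13) and of myogenic genes (uncontracted Myc 1, 0.14, or contracted Myc 2, 0.23). For translation it did so without uncontracted control 2 (-0.16), contracted control 3 (-0.03), uncontracted Myc 1 (-0.11) or contracted Myc 3 (-0.11). For ATF4 it did so without uncontracted control 3 (0.25), contracted control 1 (0.23) or 3 (0.29), uncontracted Myc 2 (0.29), or contracted Myc 2 (0.14) or 3 (0.29). Single outlying libraries were not tested.

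The libraries labelled contracted control 2 and 3 and contracted Myc 2 and 3 held Myc reads against their labels, and without them 11 of the 12 lists had a smaller median interaction in size, while that of the RNA polymerase I machinery was larger (-0.44), so that its lost call may come from fewer legs alone. The 12 lists were chosen because their interaction passed in all libraries, so smaller values are likely from that choice alone. Other sets of 4 libraries were not left out, so the count of 11 does not bear on the labels. If the labels of contracted libraries 2 and 3 were exchanged between control and Myc mice, the 100 genes that best part the uncontracted legs by genotype, leaving out Myc and genes that changed with averaged contraction, should place only the libraries numbered 1 on the side of their label. In this test 2 of the 6 contracted libraries, those labelled control 1 and Myc 1, lay on that side, with scores of -0.169 and 0.299, while control 2 and 3 scored 0.127 and 0.128 and Myc 2 and 3 scored -0.189 and -0.196. Genes chosen this way may follow the Myc level whatever set it, so the test cannot single out an exchange. Scores were centred on the 6 contracted legs, so that some had to fall on each side. An exchange of labels remains a candidate explanation, found and tested on the same data. The animals' other legs could not decide it. Legs of 1 animal as labelled correlated at only -0.122 to 0.112, and the pairs that an exchange would form at -0.103 to 0.0953. These deviations were taken from group means that rest on the labels in doubt, so low values do not show that legs of 1 animal are unalike. Contraction that raised Myc in control muscle goes with 2 of 3 contracted control libraries, which were above every uncontracted control library. It leaves unexplained contracted control 1, with 1 read, and contracted Myc 2 and 3, with 0 and 2. Over-expression absent from contracted legs goes with 2 of 3 contracted Myc libraries, which were below every uncontracted Myc library. It leaves unexplained contracted Myc 1, with 32 reads, and contracted control 2 and 3, with 10 and 59. Each prediction was met in 2 of 3 libraries, so the reads cannot decide on either explanation. Both acting together in animals numbered 2 and 3 but not 1 cannot be told apart from an exchange by these reads or scores. An exchange would in turn leave unexplained why contracted legs of Myc mice held reads as far apart as 10, 32 and 59.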

How the results depend on the processing

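Leaving out the 4 contracted libraries numbered 2 and 3, with the lone library of each contracted group assumed to vary like the others, was chosen after seeing the data. Contraction then changed 67 genes in controls, 59 in Myc mice and 107 on average, Myc changed 6 genes in uncontracted muscle, and 24 of 48 and 27 of 52 named genes in control and Myc mice kept their call. With 1 contracted leg left per group, loss of power is part of that change by construction. The calls for Myc in uncontracted muscle depend on libraries chosen by their Myc reads, which may also lower the spread of genes that vary with Myc. The contracted libraries kept, control 1 and Myc 1, also had the lowest contracted scores of immediate early genes (0.653 and 0.285, against 0.806 to 1.33). The same held for genes of mechanical stress (0.396 and 0.289, against 0.671 to 0.961). Smaller effects of contraction in these legs may thus be part of the change too, and the parts were not separated. In that setting the correlation of the contraction effects was 0.277 and that of the Myc effects 0.127. The Myc transcript was 4.47 in uncontracted muscle (adjusted p = 0.0441), 4.84 in contracted muscle and 0.37 in the interaction, the last 2 reversed, which carries no information, since the libraries were chosen by their Myc reads. The lists called numbered 7 for contraction in controls, 12 for Myc in contracted muscle and 1 for the interaction. Lists whose direction reversed there, with their medians, were ribosomal proteins in contraction of controls (0.00685), of Myc mice (0.11) and in the interaction (0.0721), and in the interaction also rRNA processing (-0.0370), translation (0.0108), glycolysis (0.0210) and fast fibre genes (-0.0971). Averaged contraction gave 0.0160 for oxidative phosphorylation, and Ighm in contraction of controls, which never passed, was 0.0239. Direction here is that of camera, which can part from the median, and the cause was not tested.

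Without a low-count filter the calls were 305 for contraction in controls, 433 in Myc mice, 24 for Myc in uncontracted muscle, 5 for Myc in contracted muscle (Krt2, Igkc, Cyp26b1, mt-Tp and mt-Tm, named after their values were seen) and 18 for the interaction. For Myc in uncontracted muscle robust dispersions and DESeq2 each called 1 gene (Timm10) and the 6 libraries compared alone called 2 (Timm10 and Nme1). Leaving out 1 library at a time gave 116 to 313 genes for contraction in controls, 147 to 517 in Myc mice, 0 to 4 for the interaction, 1 to 8 lists for Myc in contracted muscle, and r of 0.560 to 0.603 between the contraction effects. The Myc transcript then ranged from 3.69 to 7.58 for contraction in controls, from -3.26 to 0.77 for contraction in Myc mice and from -4.50 to 0.97 for Myc in contracted muscle. The correlation of contraction effects was 0.746 with the stricter filter and 0.859 over called genes. That of contraction with Myc in uncontracted muscle was -0.0294 over called genes, and none could be formed between the 2 Myc effects, as 0 genes passed. With an estimated correlation the lists called fell to 0 for contraction in controls, in Myc mice and on average, 0 for the interaction and 1 for Myc in uncontracted muscle. Fry called 9 for contraction in controls, 6 in Myc mice, 8 on average, 1 for Myc in uncontracted muscle and 0 for the interaction. The cause of these changes was not tested.

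With the replicate block on the animal, contraction changed 172 genes in controls and 228 in Myc mice and the interaction 0. The Myc transcript was 5.68 in controls (adjusted p = 0.0131) and -0.0659 in Myc mice, reversed, and the block moved no other count by over 1.5 times. Between genotypes the numbers join different animals, whose same-leg deviations correlated at -0.144 to 0.160, and that block gave 0 genes in either leg. Over all settings, 84 gene counts stayed within 1.5 times the main count, with 0 against 0 taken as kept, and 22 moved. Counts of lists called stayed within that range in 60 cases and moved in 16. For correlations, 30 stayed within 1 SE, obtained from leaving libraries out in turn, while 13 moved and 1 reversed. In all, 582 list values and 1109 gene values kept their direction and side of the threshold. Another 204 gene values and 168 list values kept their direction but no longer passed. The low-count filter, with a minimum count of 10, limits which genes were tested. In simulated data at this depth, 2-fold changes were recovered at 53.7% for contraction in controls, 92.5% for averaged contraction and 17.9% for the interaction. The size of change that can be found thus differs by comparison, and the part played by depth was not tested.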

Other observations

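The tests in this part were chosen after the results were seen. Averaged over genotypes, contraction moved some macrophage markers apart, since Cd68 (1.70 ± 0.40, edgeR adjusted p = 0.00937) and the galectin gene Lgals3 (0.997 ± 0.219, adjusted p = 0.00484) rose, whereas the complement gene C1qa (-0.60 ± 0.16, adjusted p = 0.0220) and Csf1r (-0.54 ± 0.15, adjusted p = 0.0293) fell. Cd68 had 3 reads in contracted control 1, against 6, 2 and 9 in uncontracted controls, so its rise in controls lay in contracted control 2 and 3 (11 and 21). Csf1r fell mostly in controls, since legs labelled Myc had 51, 61 and 52 reads uncontracted and 53, 50 and 40 contracted. C1qb and Lyz2, also measured, had overlapping reads in uncontracted and contracted legs (15 to 49 against 18 to 38, and 37 to 80 against 38 to 68). All 4 haemoglobin genes rose in edgeR, as did 15 of 22 immediate early genes, 13 of 28 heat shock genes and 10 of 17 genes of mechanical stress. Of 14 clock genes 5 fell and 1 rose. The list tests of this average are camera adjusted p = 0.000659 for haemoglobin, 5.54e-18, 8.81e-12 and 2.83e-15 for the next 3, and 0.107 for the clock, with adjusted p = 0.313, 0.0725, 0.0725, 0.0725 and 0.313 with an estimated correlation.

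S100a8 and S100a9, which neutrophils hold in large amounts, had 304 reads in the 6 contracted legs and 7 in the 6 uncontracted legs, a ratio of 43.9 (95% exact interval 21.1 to 110, counting error only). Of the 7 reads 5 lay in the library labelled uncontracted control 3, without which the ratio was 128 (35.2 to 1063). The 4 haemoglobin genes had 5716 against 3451 reads, a ratio of 1.68 (0.949 and 0.983 in the animals labelled control 2 and Myc 2, and 1.81 to 2.58 in the other 4). More blood of the same make-up in the contracted legs would raise both alike, but with uncontracted legs set to at least 3 reads, the S100a8 and S100a9 ratio exceeded the haemoglobin ratio in 6 of 6 animals as labelled, by a mean log2 difference of 2.61 (SD 1.20, 95% t interval over animals 1.35 to 3.86), and the lower bound was 0.876 to 1.75 without 1 animal at a time. These values argue against more blood as the whole cause but do not exclude it. The 2 genes were chosen because they had risen, legs were paired as labelled, and the animal labelled Myc 2 rests on 6 contracted reads. Neutrophils that had entered the muscle, or a change in the blood itself, may be the source, and neither was tested.

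The score of immediate early genes was lower in the contracted libraries labelled control 1 (0.653) and Myc 1 (0.285) than in the others of their group (0.806 to 1.33). The transcript Gm42418 took 0.440, 1.09, 1.04 and 0.537% of the reads of the libraries labelled contracted control 2 and 3 and contracted Myc 2 and 3, and 0.0639 to 0.298% of the other 8.

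Other splits of the same libraries were counted for each comparison. For contraction in controls the real split gave 187 genes and the highest other split 0, and for contraction in Myc mice 260 and 0, each with 1 of 10 splits as large as the real one, too few for a share under 0.05. For Myc in uncontracted legs, Myc in contracted legs and the interaction the real value was 0, so that 10 of 10 splits are as large by construction and the count decides nothing. Their highest other splits gave 0, 9 and 0. For averaged contraction, 1 of the 32 ways to exchange legs within animals as labelled, the real one, gave as many as 499 genes, and the highest other gave 247. That share is under 0.05 and is the smallest this count can give, for a comparison added after the data were seen. It argues against chance without excluding it.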
